A study of Mus musculus with 5 samples.

How the data were processed

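CD45+ cells were sorted by flow cytometry from the dispersed pancreas of 5 female NOD mice of 10 weeks, and total RNA was extracted with TriZol, labelled with biotin and hybridised to 1 array for each mouse, per the labels' protocols. The mice form 1 group, and the T2 value in ms was copied from the label of each sample. The labels name separate mice but no date, batch or array slide, so no batch could be tested. T2 fell in the order of the sample numbers. If handling or array order followed those numbers, its effects could not be told apart from those of T2. The p-values of single genes set the T2 slope against the spread of the 5 mice around the fit, moderated over genes. Those of limma's camera, a test of gene lists, set a list's genes against all others and lean on an assumed correlation between genes.

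The deposited values were probe-set intensities on a linear scale, made by the authors with RMA in Affymetrix Power Tools, per the submitters' processing notes; versions and genome build are not given in the sources used here. RMA corrects background, quantile normalizes the arrays and summarizes the probes of a set by median polish. The deposited intensities ran from 2.87 to 19435, with medians between 23.8 and 24.5 on the 5 arrays, which is how the linear scale was recognised. Equal values on several arrays were common: 46.5% of the 35556 probe sets, and 38.2% of the genes tested, had the same value on 3 or more of the 5 arrays, and 216 of the genes tested had it on all 5. Such equal values lower the residual spread of a gene. Pairs of arrays had Pearson's r between 0.980 and 0.989 across probe sets, which are not independent replicates, and no pair shared more than 31.0% of its values, so each array was counted as a sample.

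Intensities were transformed to log2. Gene names came from GEO's annotation of the platform, which lists 23410 of the probe sets; 21789 have 1 gene symbol, 1621 have several and were not named, and 12146 are unnamed here. No symbol changed when gene identifiers were matched to the RefSeq table of GRCm38.p6, and no coordinate is printed because the build behind the probe sets is not stated. For a gene with several probe sets the set of highest mean was used, giving 19938 genes, and the 6603 genes with a mean log2 intensity of at least 6 were tested. With a fixed T2 value for each mouse, log2 intensity was fitted on T2 with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with 3 residual degrees of freedom, a two-sided test and Benjamini-Hochberg adjustment with a threshold of 0.05. The 95% intervals of folds come from the moderated fit. They are not corrected for the choice of genes by lowest p or largest moderated t.

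A set of 35 gene lists was fixed before the data were examined, for cell types, cell states, pathways, handling stress and the non-immune cells of pancreas. Of their 503 distinct genes, 457 had a probe set of their own and 248 passed the filter; 30 lists had at least 3 genes past it and were tested with limma's camera at a preset inter-gene correlation of 0.01. The lists of ductal, islet endocrine, fibroblast, endothelial and erythroid cells had fewer than 3 genes past the filter and are described without it. Slopes of list means are ordinary least-squares slopes over the 5 mice. Counts are given over all genes and adjusted over the list alone. Genes named in the text followed a rule set beforehand: in each direction the 10 genes of lowest p whose slope kept its sign without each mouse, since none passed the adjusted threshold; 18 fixed genes, of which 1 is not reported here; and for each list the 4 members (2 where the list did not pass) with the largest moderated t. Other list members named, the markers of other tissue macrophages and the list of large peritoneal macrophages were chosen after their values or the main results were seen.

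On simulated data with the real residual spreads of the 6603 genes, 36% of genes with a slope of 0.1 log2 per ms, 66% with 0.2 and 96% with 0.4 were recovered at the adjusted threshold, with 7 false calls. These genes and others with a slope of 0.8, 50 of each size, were changed in the same data. Strong genes ease the adjusted threshold for weak ones, so the shares may be too high for data with few changed genes. A simulated list of 13 independent genes with a slope of -0.17 was called, and 6 of 100 unchanged lists fell under an unadjusted p of 0.05. The simulated genes vary independently, unlike the measured ones.

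Alternatives fixed beforehand were other expression filters, renormalized or centred arrays, the mean of all probe sets, all probe sets, the rank of T2, other variance models, array weights, an acinar covariate, a threshold of 0.10, each mouse left out, an estimated inter-gene correlation and fry. Added after the data were seen were the removal of genes with equal values, a stress covariate, the exact permutation of T2 and the complement list without macrophage genes.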

Results

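Gene expression was measured in CD45+ cells, the leukocytes, sorted from the pancreas of 5 female NOD mice of 10 weeks, a strain that develops autoimmune diabetes spontaneously. Each pancreas had been imaged by MRI just before it was taken, and each mouse carried 1 T2 value, the transverse relaxation time of the tissue in ms. T2 was 35.3 ms in mouse 1, 35.24 ms in mouse 2, 32.77 ms in mouse 3, 30.02 ms in mouse 4 and 28.98 ms in mouse 5. The labels gave no other grouping, so the comparison was between expression and T2 across the 5 mice, and the question was which transcripts of the pancreatic infiltrate varied with the MRI signal. The labels do not say whether a contrast agent was given or which T2 values go with more severe insulitis, and no such reading is attached to high or low T2 here. Each mouse was hybridised to 1 array of 35556 probe sets, and the number of arrays limits the precision of every slope. With fewer than 6 mice no correlation coefficient was computed. Slopes are given as the change in log2 intensity per ms of T2 with its standard error (n = 5), and a fold is the fitted ratio over the 6.32 ms between the lowest and the highest T2.

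Ptprc, which encodes CD45 itself, was similar in the 5 mice, with a log2 intensity of 11.06 ± 0.10 (SD, n = 5). The B cell list averaged 8.44 ± 0.39 and the T cell list 8.36 ± 0.29 (SD, n = 5), as means over the 15 members of each past the expression filter. Transcripts of islet endocrine cells stayed near the lower end of the scale, with a mean of 3.79 ± 0.058 (SD, n = 5) over 15 genes and an Ins2 intensity between 18.1 and 18.5. Fibroblast and pericyte genes averaged 4.31 ± 0.065 over 12 genes, ductal genes 4.07 ± 0.057 over 9 genes, endothelial genes 4.61 ± 0.044 over 12 genes, and genes of erythroid cells and platelets 4.16 ± 0.078 over 7 genes (SD, n = 5). Of the acinar list 7 genes passed the expression filter. Ctrb1, a chymotrypsinogen, had a log2 intensity of 8.19 ± 0.45 and Cpa1, a carboxypeptidase, 7.43 ± 0.38 (SD, n = 5), with the highest values of both in mouse 1. The acinar list had a T2 slope of -0.0021 ± 0.059 over its 7 members past the filter.

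Lymphocyte genes differed between mice of nearly the same T2. Mice 1 and 2, with T2 values of 35.3 and 35.24 ms, had T cell list means of 8.01 and 8.78 and B cell list means of 8.91 and 8.03. Cd8a, the CD8 alpha chain of cytotoxic T cells, read 221 in mouse 1 and 594 in mouse 2. The neutrophil list ranged from 6.85 in mouse 4 to 8.76 in mouse 3, and Ngp, a neutrophil granule protein, from 4.70 to 8.38 in the same 2 mice. These lists had T2 slopes of 0.016 ± 0.056 for T cells, -0.027 ± 0.075 for B cells and -0.024 ± 0.15 for neutrophils, each smaller than its standard error.

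Macrophage genes were higher in the mice with lower T2. All 13 macrophage genes past the filter had a negative slope, as did 67.9% of all genes tested, and the mean of the list changed by -0.17 ± 0.020 log2 per ms, a fold of 2.10 between the lowest and the highest T2. No member passed over all genes tested, and 9 passed when adjusted over the list alone. Apoe, a lipoprotein that macrophages secrete, had a slope of -0.24 ± 0.020 and a fold of 2.81 (95% interval 2.19 to 3.59). C1qa, a chain of complement C1q, had a fold of 3.05 (2.14 to 4.33), and Adgre1, an adhesion-type receptor used as a macrophage surface marker, a fold of 2.68 (1.92 to 3.75). Cd14, a receptor for bacterial lipopolysaccharide, had a slope of -0.15 ± 0.021 and a fold of 1.95. Csf1r, Cd68, Selenop and Sirpa did not pass over the list alone, with slopes of -0.07, -0.07, -0.02 and -0.03. Of the 7 members under the filter, Mertk, a receptor for apoptotic cells, had a slope of -0.16 ± 0.012 and a fold of 2.01. Mrc1 had a slope of -0.05 ± 0.051, and Cd163, Lyve1, Folr2, Fcgr1 and Trem2 had slopes between -0.01 and 0.02.

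**Figure D1:**
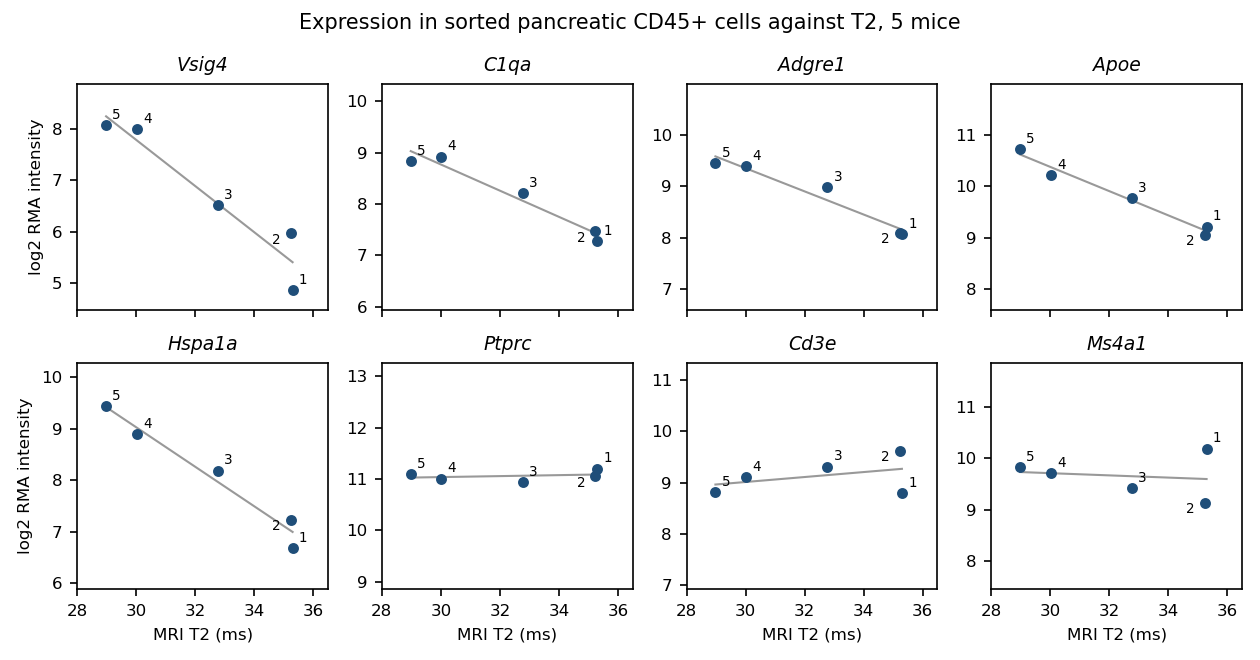
Log2 RMA intensity (vertical axis, the same span in each panel) against MRI T2 in ms for 8 genes; each point is 1 mouse with its number and the line is the fitted slope. Vsig4, C1qa, Adgre1, Apoe and Hspa1a read lower at higher T2, while Ptprc stayed between 10.94 and 11.20 and Cd3e and Ms4a1 differed most between mice 1 and 2.

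Complement genes showed the same direction. Of 13 genes past the filter 12 had a negative slope, the list mean changed by -0.19 ± 0.020 log2 per ms, and 9 genes passed when adjusted over the list alone, with none over all genes. Vsig4, the macrophage complement receptor CRIg, had the steepest slope of the list. Its intensity was 29.1 in mouse 1, 62.5 in mouse 2, 91.2 in mouse 3, 255 in mouse 4 and 268 in mouse 5, a slope of -0.45 ± 0.071 and a fold of 7.14 (95% interval 2.97 to 17.2; limma adjusted p = 0.364 over all genes). Leaving out each mouse in turn moved this slope between -0.52 and -0.37. The values of mice 1 and 2, log2 4.86 and 5.97, lie under the filter, and that of mouse 1 is near the median intensity of its array, 24.3, so the size of the fold rests on low signal. C4b, a complement C4 gene, had a fold of 3.10 (2.15 to 4.46) and Itgam, the CD11b chain of complement receptor 3, a fold of 2.38 (1.94 to 2.92). Itgax, the partner chain of complement receptor 4 and a dendritic cell marker, had a slope of 0.00037 ± 0.0047, and its value was equal on 4 of the 5 arrays.

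Both lists passed limma's camera test with its preset inter-gene correlation of 0.01, with adjusted p = 1.27e-11 for macrophages and 8.22e-09 for complement over 30 lists. With an estimated correlation, 0.17 for macrophages and 0.25 for complement, the calls were lost, at adjusted p = 0.325 and adjusted p = 0.463. A list of lipid handling genes, described below, lost its call too, at an estimated correlation of 0.016, near the preset 0.01. The size of the correlation alone thus does not account for such a loss. limma's fry, which asks only whether a list's genes move one way, gave adjusted p = 0.0233 for each. An exact permutation of T2 over the 120 orders of the mice gave p = 0.025 (two-sided; adjusted 0.188) for the macrophage list mean and p = 0.0417 (adjusted 0.208) for complement, where the smallest p the design allows is 0.00833. A single list at that smallest p has an adjusted p of 0.25 over 30 lists, so the adjusted permutation p had little room to pass. The complement list still passed camera without the members it shares with the macrophage list (adjusted p = 1.21e-05). That was run at the preset correlation and kept Vsig4, Itgam and C4b, which are counted below among genes of peritoneal macrophages. It thus does not set complement apart from macrophages. Markers of large peritoneal macrophages, a list added after these results were seen, had a mean slope of -0.20 ± 0.039 over 11 genes, and the list of dissociation stress genes had -0.074 ± 0.019.

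Genes of lipid handling and phagocytosis were also higher in the mice with lower T2. All 12 members past the filter had a negative slope, with a list mean of -0.11 ± 0.013 log2 per ms, and 3 passed when adjusted over the list alone, with none over all genes. These were Apoe, which the macrophage list also holds, the scavenger receptor Msr1 with a fold of 2.00 (95% interval 1.65 to 2.42) and Axl, a receptor for apoptotic cells, with a fold of 1.84 (1.46 to 2.33). Ctsb, the lysosomal protease cathepsin B, had a fold of 1.47 (1.11 to 1.94) and did not pass. The list passed camera (adjusted p = 5.18e-07; adjusted p = 0.325 with an estimated correlation). In the alternatively activated and resident macrophage list, which did not pass camera (adjusted p = 0.0528), 4 genes were past the filter, and Vsig4 and Timd4, a receptor for phosphatidylserine, passed over the list alone. Timd4 had a fold of 2.77 (1.31 to 5.86). This list passed camera with no filter (adjusted p = 0.000644), with renormalized (0.000827) or centred arrays (0.000213), on ranks of T2 (0.0371), with the acinar covariate (0.0241), without genes of equal values (0.0098) and mixed fry (0.0295). It did not pass with an estimated correlation (adjusted p = 0.551), a filter of 7 (0.426), array weights (0.0996), the stress covariate (0.186), directional fry (0.0719) or the exact permutation (0.188), nor without any 1 mouse (0.0652 to 0.146).

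The lists of mast cell genes and of stress genes were called lower at higher T2 by camera, and few or none of their members passed on their own. Cpa3, a mast cell carboxypeptidase, had a slope of -0.23 ± 0.059, Tpsb2, a tryptase, -0.17 ± 0.054 and Mcpt4, a chymase, -0.20 ± 0.069, while Kit had -0.06 ± 0.033. These were the 4 genes past the filter of a list of mast cells, basophils and eosinophils, and none passed over the list alone or over all genes (camera adjusted p = 0.0112; adjusted p = 0.71 with an estimated correlation). With no filter 9 of 14 slopes of this list were negative (adjusted p = 0.0729), and directional fry gave adjusted p = 0.311. Leaving out mouse 1 or mouse 4 ended this call, at adjusted p of 0.0639 and 0.0698. In the immediate early and dissociation stress list 13 of 15 slopes were negative, with a list mean of -0.074 ± 0.019, and 1 member passed over the list alone and none over all genes. This was Hspa1a, an inducible heat shock protein, with a fold of 5.38 (95% interval 3.28 to 8.82). Dnajb1, its co-chaperone, had a fold of 1.95 (1.26 to 3.04), Jun a fold of 1.62 (1.18 to 2.23) and the phosphatase gene Dusp1 a fold of 1.66 (1.15 to 2.39). The stress list passed camera (adjusted p = 0.0112; adjusted p = 0.71 with an estimated correlation), directional fry gave adjusted p = 0.159, and leaving out mouse 2, 3 or 5 ended the call at adjusted p of 0.125, 0.0526 and 0.131.

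**Figure D2:**
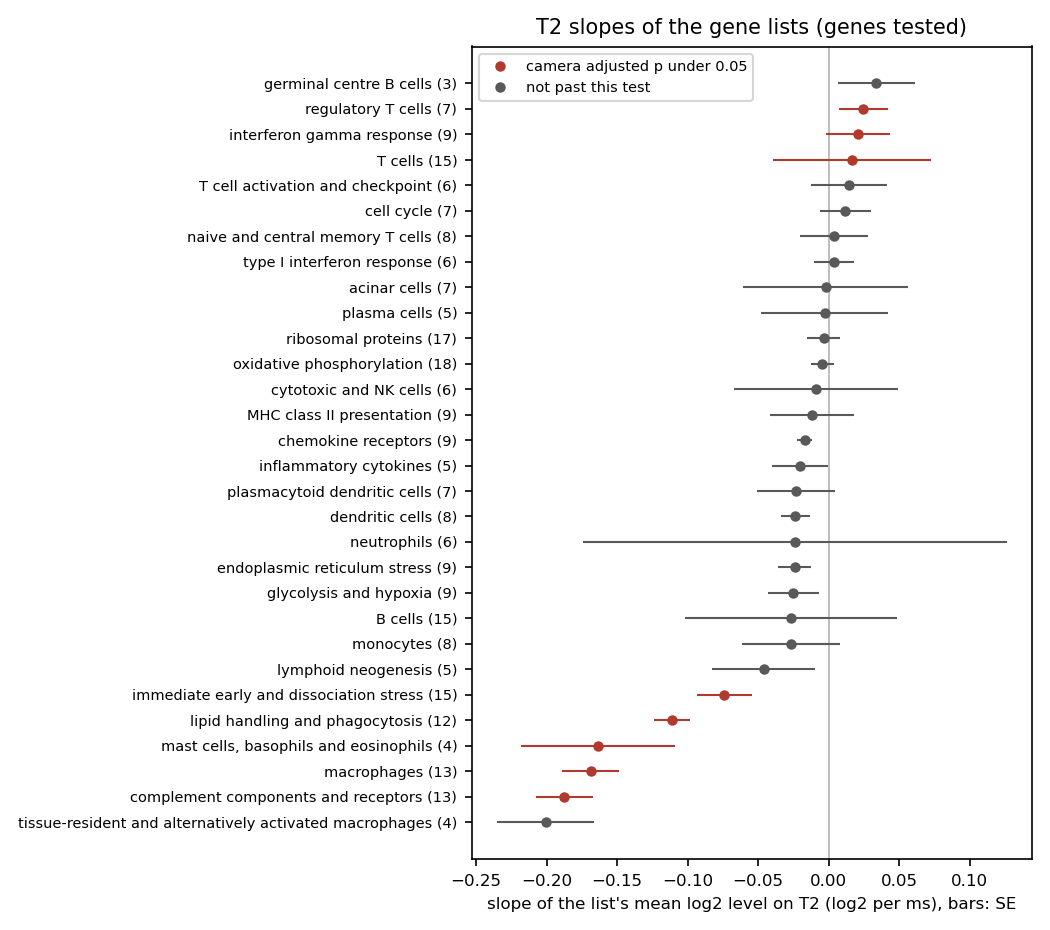
Slope of each gene list's mean log2 intensity on T2 (horizontal axis, log2 per ms) with its standard error as a bar, for the 30 lists tested in 5 mice; the number of genes tested is in brackets and red marks an adjusted p under 0.05 in camera with the preset correlation. The alternatively activated and resident macrophage list, which did not pass camera, lies lowest, at -0.20. The macrophage, complement, lipid and mast cell lists lie between -0.19 and -0.11, and the neutrophil list has the widest bar, ± 0.15.

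The lists of T cells, regulatory T cells and the interferon gamma response were called in the other direction by camera, each at adjusted p = 0.0112, on small slopes. Camera sets a list against all other genes, whose median slope was -0.0074, so a list with slopes around 0 can be called higher. The list means had slopes of 0.016 ± 0.056, 0.025 ± 0.018 and 0.021 ± 0.023, and no member passed over the list alone or over all genes. Foxp3, the lineage factor of regulatory T cells, had a slope of 0.05 ± 0.032, Tnfrsf4 (OX40) 0.05 ± 0.026, Cd3e 0.05 ± 0.056 and Irgm1, an interferon-inducible GTPase, 0.06 ± 0.039. With an estimated correlation the adjusted p was 0.908 for T cells, 0.551 for regulatory T cells and 0.71 for interferon gamma. Each of these calls was lost when the arrays were centred on their medians (adjusted p of 0.215, 0.0887 and 0.0887) and when mouse 2 or mouse 5 was left out, with adjusted p of 0.156 and 0.746 for T cells, 0.125 and 0.0601 for regulatory T cells and 0.161 and 0.846 for interferon gamma. The T cell list had the other direction without mouse 2, and the regulatory T cell call was also lost without mouse 4 (adjusted p = 0.283). With centred arrays 6 lists were called lower at higher T2 and 0 higher, against 5 and 3.

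The other 22 lists did not pass camera. Cd4 had a slope of 0.0083 ± 0.064, Cd8a -0.02 ± 0.095, the plasmacytoid dendritic cell gene Siglech -0.06 ± 0.086 and the cytokine gene Il1b -0.07 ± 0.084. S100a8, a neutrophil calcium-binding protein, had a slope of -0.00036 ± 0.15, and Pecam1, an endothelial and leukocyte adhesion molecule, -0.0061 ± 0.023. Fscn1, an actin-bundling protein of mature dendritic cells, had a slope of -0.17 ± 0.048, and Cxcl13, a B cell chemoattractant, -0.20 ± 0.067, against list means of -0.02 ± 0.010 for dendritic cells and -0.05 ± 0.036 for lymphoid neogenesis. Fn1 and Itgam were the 2 members of the monocyte list that passed over the list alone, at -0.16 ± 0.016 and -0.20 ± 0.017, while the list mean was -0.03 ± 0.034 and its median 0.015. Pfkl, a phosphofructokinase of glycolysis, was the 1 member of the glycolysis list that passed over the list alone, at -0.06 ± 0.0097. For acinar, ribosomal protein, B cell, neutrophil, dendritic cell and MHC class II lists, among others, camera gave the direction higher while the mean slope was negative. Cytotoxic and NK cell, plasma cell, germinal centre, cell cycle, MHC class II, type I interferon, ribosomal protein and oxidative phosphorylation lists had mean slopes between -0.012 and 0.034. Ncr1, Ins2, Prss2, Col3a1 and Ifng lay under the filter.

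Over single genes, 0 of 6603 passed limma's moderated test of the T2 slope at an adjusted p under 0.05. At an unadjusted p under 0.05 there were 349 genes, against 330 that this threshold gives by chance at its nominal rate, and 303 of them had a negative slope; of all 6603 genes 4482 had a negative and 1905 a positive slope. On simulated data with the real residual spreads, 6.14% of unchanged genes fell under this threshold, more than the nominal 5%, so the total of 349 is no excess over that rate. The simulated genes vary independently, so they cannot judge the share of negative slopes. Of 100 orders of T2 over the mice, the real one included, 14 gave at least 349 genes. The number of genes under this threshold was 660 without mouse 1 and 531 without mouse 4, with 0 past the adjusted threshold in both. With renormalized or centred arrays 4 genes passed. The lowest adjusted p was 0.0951, shared by 3 genes. Acaca, the acetyl-CoA carboxylase of fatty acid synthesis, had a fold of 1.77 (95% interval 1.65 to 1.90), Idh1, the cytosolic isocitrate dehydrogenase, 2.09 (1.90 to 2.31) and Ecm1, an extracellular matrix protein, 2.46 (2.18 to 2.79), each higher at lower T2. These 3 genes were picked for lowest p, so their intervals are likely too narrow. With genes of equal values left out, the standard errors of their slopes were 0.0156, 0.0162 and 0.0169. In the main fit they were 0.00566, 0.00792 and 0.00999. Garnl3, Itsn1, App, Sorbs3, Hipk2, Itgam and Apoe completed the 10 negative slopes of lowest p, with folds from 1.39 for Sorbs3 to 2.81 for Apoe. The 10 positive slopes of lowest p were smaller or less certain. Frmd6 had a fold of 1.58 between the highest and the lowest T2 (1.36 to 1.82; limma adjusted p = 0.266), and the small nucleolar RNAs Snord55 and Snord22 had folds of 1.73 (1.40 to 2.12) and 1.54 (1.25 to 1.90). Mir6516, Hmx2, Ppcs, Ppp1r14b, Tent5b, Gm10139 and E130304I02Rik had slopes between 0.04 and 0.13. These 20 slopes kept their sign when each mouse was left out, by the rule that chose them. Some positive slopes shrank under an alternative, that of Snord22 from 0.099 to 0.039 and that of Gm10139 from 0.126 to 0.047. With genes that had equal values on 3 or more arrays left out, an alternative chosen after the data were seen, 35 genes passed, all with negative slopes.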

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

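The tests in this part were chosen before the values were seen. In 30 list means and 103 named genes, 1 mouse stood apart from the other 4 in 1 list and 5 genes, by the gap to its nearest neighbour as a share of the whole range; chance alone gives about 1 in 20, and 2 of the 5 genes had equal values on 3 or more arrays. The germinal centre B cell list was lowest in mouse 5, at 6.27 against 6.62 to 6.68 in the others (gap share 0.854), and its member Basp1 read 5.78 there against 6.41 to 6.59 (0.782). Foxp3 was highest in mouse 2, at 6.55 against 5.95 to 6.08 (0.782). Nkg7, a cytotoxic granule protein, was lowest in mouse 1, at 7.01 against 7.99 to 8.36 (0.722), and H2-Eb1, an MHC class II chain, was lowest in mouse 2, at 10.32 against 10.63 to 10.73 (0.756). Itgax had a gap share of 1 because 4 arrays held the same value, 6.68, and mouse 3 had 6.72.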

How the results depend on the processing

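The removal of genes with equal values, the stress covariate and the exact permutation were chosen after the data were seen. No paired analysis was possible because the mice form 1 group. The macrophage, complement and lipid lists stayed past camera's threshold in every filter, normalization, variance model, covariate and left-out mouse that was run, with adjusted p from 8.60e-07 to 1.95e-12, from 3.23e-05 to 7.79e-11 and from 9.46e-05 to 7.26e-06 without 1 mouse. They lost it with an estimated correlation (0.325, 0.463 and 0.325) and with the exact permutation (0.188, 0.208 and 0.188), where, with a smallest p of 0.00833, no list can pass unless at least 6 pass together, so that loss says little. The count of 8 lists became 0 in both of these and 3 with directional fry, and ran from 5 without mouse 5 to 14 without mouse 1. The count of 0 genes became 3 with a filter of 7 or a threshold of 0.10, 4 with renormalized arrays, centred arrays or array weights, and 35 without genes of equal values; it stayed 0 with the other variance models and without any 1 mouse, and an unadjusted p under 0.05 was held by 219 genes (filter of 7) to 660 genes (without mouse 1). The other called lists were lost as follows, with adjusted p. T cells: 0.395 with no filter, 0.145 renormalized, 0.215 centred, 0.260 on ranks, 0.908 with estimated correlation, 0.968 and 0.965 with directional and mixed fry, 0.938 by permutation, and 1.48e-11 to 0.746 without 1 mouse, reversed at 0.156 without mouse 2. Regulatory T cells: 0.0647 renormalized, 0.0887 centred, 0.0748 on ranks, 0.551 estimated, 0.711 and 0.965 with fry, 0.692 by permutation, 0.688 with the stress covariate, and 0.00063 to 0.283 without 1 mouse. Interferon gamma: 0.129 with no filter, 0.0887 centred, 0.0933 with array weights, 0.71 estimated, 0.968 and 0.965 with fry, 0.882 by permutation, and 0.000412 to 0.846 without 1 mouse. Mast cells: 0.0729 with no filter, 0.71 estimated, 0.311 and 0.204 with fry, 0.208 by permutation, and 0.011 to 0.0698 without 1 mouse. Stress: 0.0523 with array weights, 0.71 estimated, 0.159 with directional fry, 0.188 by permutation, and 0.00113 to 0.131 without 1 mouse. With the stress covariate camera's direction turned for T cells (0.0162), interferon gamma (0.0218), cell cycle (0.0199), germinal centre B cells (0.0177) and the stress list itself (0.576), which that covariate holds by construction. Without mouse 1 camera's direction turned to lower and was called for B cells (2.42e-05) and acinar cells (0.0204, with a range of 0.00035 to 0.527 without 1 mouse). Camera's direction is relative to the other genes, and both list means already had negative slopes over all 5 mice (-0.027 and -0.0021). Otherwise the cause was not tested. Of 434 results of the other lists, 406 stayed on the same side and 24 were called in the same direction, among them the resident macrophage list in 7 settings, from 0.000213 with centred arrays to 0.0371 on ranks. Of 1621 slopes of named genes under alternatives, 77 had another sign, in genes not called in any of them. The 51 marker levels moved by less than 1 SD between mice. Low signal limits the markers under the filter, and no array was replicated.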

Other observations

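Tests on the orders of T2 and on the peritoneal macrophage markers had their outcome stated before they were run, except the order test of the macrophage list; that test and those on lymphocytes, stress, equal values and the slope of Vsig4 were chosen after the results were seen. Several genes known from large peritoneal macrophages, the resident macrophages of the peritoneal cavity, had negative T2 slopes in the first results. Fn1, fibronectin, had a slope of -0.16 ± 0.016, Ltbp1, a binding protein of latent TGF-beta, -0.29 ± 0.028, Saa3, a serum amyloid protein, -0.31 ± 0.033 and Garnl3 -0.23 ± 0.013. With Vsig4, Timd4, Itgam, C4b, Ecm1 and Cxcl13 these 10 genes had a mean slope of -0.25 ± 0.032, and 6 of them are in the lists set beforehand. The 10 were put together after their slopes were seen, so this mean is no separate evidence.

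The hypothesis drawn from these genes was that the macrophage genes follow the amount of large peritoneal macrophages in the sorted cells. A list of 13 further markers, Gata6, Prg4 and Alox15 among them, was written before the values of any of them were looked at. Of the 11 with a probe set, none is in another list, and the mean slope was -0.20 ± 0.039 log2 per ms, past the -0.10 set beforehand, a fold of 2.41. Thbs1 (-0.32 ± 0.044), Tgfb2 (-0.28 ± 0.045), Serpinb2 (-0.27 ± 0.071), Prg4 (-0.26 ± 0.038) and F5 (-0.26 ± 0.048) were the steepest, Alox15 had -0.26 ± 0.050 and Gata6, the transcription factor that defines these cells, -0.16 ± 0.054, and 9 of the 10 past the filter had an unadjusted p under 0.05 in limma. Markers of liver and spleen macrophages, such as Clec4f and Spic, had a mean slope of -0.0016 ± 0.019 over 10 genes, of which 4 lay past the filter. Markers of interstitial macrophages had -0.036 ± 0.0065 over 11 genes, of which 10 lay under the filter. A sort on CD45 would keep peritoneal cells.

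The values bear on 2 other explanations of the macrophage pattern as its whole cause but exclude neither. Fewer lymphocytes in the sort would raise other leukocytes alike. The macrophage mean fell away from the dendritic cell mean by -0.12 ± 0.003 log2 per ms with all genes, and by -0.15 ± 0.013 with genes past the filter. These differences go against a rise shared by both lists. The dendritic cell list is no clean control, since it shares Ccr7 with the naive T cell list and only 8 of its 15 genes passed the filter. The difference to neutrophils, -0.097 ± 0.12, decided nothing. With the stress list mean as a covariate the macrophage slope was -0.23 ± 0.035 against -0.17 without it. The stress list was itself lower at higher T2, at -0.074 ± 0.019, and stands in for handling only in part. This fit therefore cannot exclude handling. Chance is not excluded: 3 of the 120 orders of T2 gave a macrophage slope as far from 0 as the real 0.169 (highest other 0.172), but the list was picked from 30 after the results were seen, and 6 of 100 drawn orders gave it a camera p as small, the real one included. Also open is whether the peritoneal markers may come from cells carried over from the cavity or surface of the organ in differing amounts, or from macrophages within the pancreas that share these genes and differ with the MRI signal. Both allow a negative slope such as the -0.20 seen, and these arrays cannot separate them.

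Vsig4, a gene named beforehand, had the steepest slope of the peritoneal macrophage markers, and its comparison with them was chosen after that was seen. Its slope lay below the mean of 20 other markers by -0.23 ± 0.052 log2 per ms, and the slopes of those single markers ran from -0.32 to -0.03. Some of these markers had been listed after their negative slopes were seen. Vsig4 reads near background in mouse 1, but its slope stayed between -0.52 and -0.37 when each mouse was left out in turn. Markers can differ in slope through background signal or other cells that express them, so the difference decides nothing about its cause.

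The number of genes past the threshold differed with the treatment of equal values. Genes with 3 or more equal arrays made up 99.7% of the 5% of genes with the lowest residual spread, against 38.2% of all genes, which equal values bring about by construction. Without them the prior degrees of freedom rose from 0.861 to 3.04 and 35 genes passed limma's adjusted threshold, all higher at lower T2. Of these, 11 are in the peritoneal macrophage lists. Among the 11 only Thbs1, Tgfb2 and Prg4 come from the list written before its values were looked at. The rest, such as Ltbp1, Saa3 and Vsig4, were listed after their slopes were seen, so their overlap is no separate evidence. Leaving out genes with equal values favours those that vary between mice, so the 35 are open to that selection. Where the equal values come from was not tested.

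The number of calls did not set the real T2 order apart from others. Of 100 orders, the real one included, 68 gave at least 8 lists past camera's threshold (highest other 15), so chance cannot be excluded for the count of lists with the preset correlation. For genes at an unadjusted p under 0.05, 14 of 100 orders gave at least the real 349 (highest other 611).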
